A study of Homo sapiens with 12 samples.

How the data were processed

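RNA was measured by poly-A RNA sequencing in 12 libraries of CUTLL1, a human T-cell acute lymphoblastic leukaemia line with a rearranged, constitutively active NOTCH1 gene. The labels place the libraries in 4 groups of 3, either solvent (DMSO) or 1 µM Compound E, an inhibitor of gamma-secretase (GSI), harvested after 12 or 48 h. Per the labels' protocols, total RNA was prepared with on-column DNase treatment before poly-A selection. The labels do not say whether replicates came from separate cultures, so p-values measure the spread between these libraries only.

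Per the submitters' processing notes, the authors used the genome build hg19, FastQC 0.10.1, TopHat2 2.0.10, HTSeq 0.6.1 and DESeq2, for which no version is given. The order, settings and role of these tools, the gene annotation and whether counting used strand are not given in the sources used here. The deposited values are a signal, read counts per gene divided by a size factor of the library, for 62069 Ensembl gene identifiers.

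In each library the values were whole multiples of the smallest value above 0, so that whole reads could be recovered. In every library 100% of the values came out whole within a tolerance of 0.01, and the largest distance from a whole number was 0.000713718. Recovered totals ranged from 73939612 to 160702764 reads per library. A count test on these reads was run beside the main test, and edgeR's quasi-likelihood test called 4201 genes in the 12 h comparison of treatments, 1919 in the 48 h comparison, 931 between the DMSO groups and 740 between the GSI groups.

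Genes with a deposited value of at least 10 in at least 3 libraries were kept, which left 19281. The main test was limma 3.58.1 in R 4.3.3 with a trended prior on log2(value + 1), fitted to all 12 libraries with a mean per group and no replicate term. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes kept. Fold changes are on the log2(value + 1) scale, which understates changes of low genes, and SE denotes the moderated standard error. Every adjusted p of a single gene below comes from this limma fit unless another tool is named.

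Before the data were examined, 34 gene lists were fixed, of which 30 had at least 5 genes kept and were tested with camera at a preset inter-gene correlation of 0.01, adjusted over lists within each comparison. Camera with an estimated correlation and fry were run beside it. A list of hypoxia response genes was added after the data were seen and is named as such wherever it appears. Its camera p-values were adjusted over all 31 lists, while those of the 30 lists were adjusted without it. The hypoxia list shared genes with lists fixed beforehand, among them LDHA with glycolysis and BNIP3L with autophagy and lysosome. Results for these lists are therefore not independent of one another.

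Genes were named by a rule fixed beforehand. It took, for each treatment comparison, the 6 largest rises and 6 largest falls among called genes with a mean of at least 100 in the higher group and no overlap between groups. For the change in DMSO over time it took 5 in each direction. All kept NOTCH1 target genes were named, with the 3 members of smallest p from each list called and up to 2 from each list not called. For long non-coding RNAs it took 3 in each direction with a mean of at least 50. The comparison of the GSI groups over time was added after the data were seen, and the rule for DMSO over time was applied to it, as was the rule for lists and long non-coding RNAs to both comparisons over time. For the difference between the treatment effects limma without a replicate term called 0 genes (875 at an unadjusted p under 0.05), so none was named there, although DESeq2 called 61 and limma with a block within treatment 1177. Not every gene taken by the rule is reported. Other genes are said to have been chosen after their values were seen.

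Gene symbols came from a table of identifiers, which gave a symbol to 39007 of the 62069 identifiers and to 16495 of the 19281 kept. Features without a symbol were not named. Biotypes came from GENCODE 29, which matched 18344 of the kept genes, 13445 of them protein-coding and 2987 long non-coding. Because that annotation is on a later genome build than the authors used, no coordinates are given. Reads of genes that overlap or run antisense to one another cannot be told apart without strand, and reads of T-cell receptor and immunoglobulin segments or HLA genes may be split between near-identical copies, so values of such genes are uncertain.

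The test was checked on simulated reads drawn from the real means and library sizes with 200 changed genes. For the 12 h comparison of treatments, over 19007 genes, it recovered 43.3% of the 67 genes changed 1.5-fold, 56.7% of those changed 2-fold and 89.4% of the 66 changed 4-fold, with 6 calls among unchanged genes. For the 48 h comparison, over 19023 genes, the shares were 38.8%, 68.7% and 98.5%, with 8 such calls. Between the DMSO groups they were 31.3%, 74.6% and 97.0% over 19008 genes, with 6 such calls, and between the GSI groups 28.4%, 71.6% and 92.4% over 18992 genes, with 3. For the difference between the treatment effects, over 18993 genes, they were 13.4%, 52.2% and 84.8%, with 4. Libraries were drawn independently around 1 mean per gene, without the shared deviations of same-numbered libraries described below. The 200 changed genes were also fewer than the 768 to 4144 called between groups. The shares may therefore not hold for these data.

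Replicate numbers were shared by the 4 groups, and pairing was checked from the correlation across genes of deviations from the group means. Same-numbered libraries deviated together between the DMSO groups, with correlations of 0.545 to 0.612, between the GSI groups, with 0.400 to 0.545, and between the groups at 48 h, with 0.103 to 0.157. At 12 h the range was 0.0676 to 0.272, so not every pair passed 0.1. The mean was 0.145 at 12 h and 0.121 at 48 h. By the limit of 0.1 for every pair, the numbers were treated as pairing the libraries in the 48 h comparison and in both comparisons over time. Values from a fit with a replicate block shared by all 4 groups are given there for counts of genes and for lists whose call changed. Counts over time are also given with a block within each treatment, where deviations were shared most. Calls of single genes come from the fit without a block. Where the numbers pair the libraries, a gene given as not called may therefore pass once the pairing is used. With the block within treatment, 79 of 207 results for named genes over time did so. Replicates within a group differed by more than sampling noise, with a chi-square per degree of freedom of at least 40.9 over genes, so none was counted as a repeat deposit.

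Alternatives were other scalings (TMM and upper quartile), pseudocounts of 0.5 and 5, no filter and a filter of 50, the replicate block, only the groups compared, edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads, leaving out each library and stricter thresholds. Reads thinned to the shallowest library, a block within each treatment and a fit without both libraries numbered 2 and labelled GSI were added after the data were seen, the last because these libraries stood nearer the DMSO libraries in hypoxia response genes and in a principal component analysis. The agreement of 2 comparisons was set against 10 splits that move same-numbered libraries together, also chosen after the results were seen.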

Results

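The series measured poly-A RNA in CUTLL1 cells under solvent or the gamma-secretase inhibitor Compound E (1 µM) at 12 and 48 h, with 3 libraries in each of 4 groups. Gamma-secretase releases the active intracellular part of NOTCH1, so the treatment comparison asks which transcripts, coding or long non-coding, depend on NOTCH1 signalling in these leukaemia cells. Recovered depth was 115899123 ± 6442725 reads (SD, n = 3) in the DMSO 12 h group, 86037870 ± 13619899 (SD, n = 3) in the GSI 12 h group, 127001043 ± 32975239 (SD, n = 3) in the DMSO 48 h group and 93986428 ± 34457594 (SD, n = 3) in the GSI 48 h group. A gene at the filter value of 10 therefore rests on few reads, and its fold change carries counting error as well as the spread between libraries.

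The 16 NOTCH1 target genes of the list fixed beforehand were examined first, because they check the labels. NRARP (ENSG00000198435), a feedback inhibitor of Notch signalling, had a normalised read count of 42352 ± 6407 (SD, n = 3) in libraries labelled DMSO 12 h, 21930 ± 4507 in those labelled GSI 12 h, 3030 ± 627 in those labelled DMSO 48 h and 1701 ± 337 in those labelled GSI 48 h. DTX1 (ENSG00000135144), a ubiquitin ligase of the pathway, had 84822 ± 9059, 61031 ± 11544, 11601 ± 1137 and 8245 ± 887 in the same order of groups. For 13 of the 16 genes the differences between the 48 h and 12 h labels, within either treatment, were larger than those between the GSI and DMSO labels at either time. The 3 exceptions were NOTCH1 itself, HEY2 and IL7R. The list median changed by −0.49 (log2) between GSI and DMSO labels at 12 h and by −0.35 at 48 h, against −1.72 between 48 h and 12 h labels in DMSO and −1.40 in GSI. An inhibitor of gamma-secretase is known to lower these genes. Under the GSI label 7 of 16 were called lower at 12 h and 3 of 16 at 48 h, against 11 and 12 between the time labels in DMSO and GSI. Camera's adjusted p between the treatment labels was 0.00893 and 0.00636, and 0.469 and 0.553 with an estimated correlation. This order leaves open whether the labels of the GSI 12 h and DMSO 48 h libraries are as intended. The groups are therefore given throughout as the libraries labelled so, and each direction below is drawn from those labels.

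**Figure D1:**
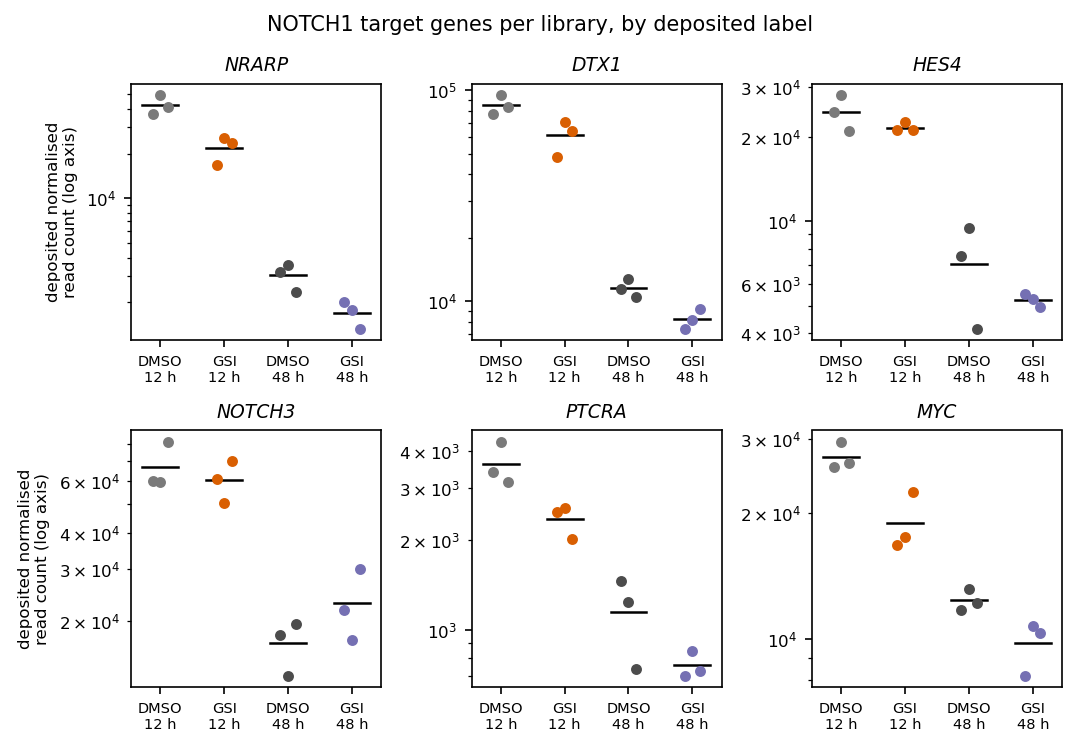
Deposited normalised read counts (log axis) of 6 NOTCH1 target genes in each of the 12 libraries, by deposited label, with points for libraries and black lines for group means. NRARP means were 42352 and 21930 in the libraries labelled DMSO 12 h and GSI 12 h, and 3030 and 1701 in those labelled DMSO 48 h and GSI 48 h.

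At 12 h, 14 of 21 glycolysis genes were higher and 27 of 29 ribosome biogenesis genes lower in libraries labelled GSI than in those labelled DMSO. Camera's adjusted p was 3.42e-07 and 1.45e-19, and 0.480 and 0.469 with an estimated correlation. ADM (ENSG00000148926), which encodes the vasodilator peptide adrenomedullin, rose from 25.6 ± 21.5 to 2426 ± 1360 (SD, n = 3; log2 fold change 6.59 ± 0.75 SE, adjusted p = 0.00112). MIR210HG (ENSG00000247095), the host transcript of the hypoxia-induced miR-210, rose from 127.7 ± 43.0 to 3850 ± 2303 (log2 fold change 4.78 ± 0.56 SE), and PFKFB4, an enzyme that sets fructose-2,6-bisphosphate levels, from 391.4 ± 69.6 to 9093 ± 5627 (4.30 ± 0.58 SE). The other largest rises were FGFBP2 (log2 fold change 5.64), PPFIA4 (5.28) and LSP1 (4.80). Among the largest falls were ACTL8 (−2.56), the calcium release channel RYR3 (−2.39), the potassium channel KCNJ2 (−2.12), the growth factor FGF22 (−2.08) and the vasopressin receptor AVPR2 (−1.96).

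Of the glycolysis list, 14 of 21 genes rose and 1 fell at 12 h (19 and 1 when adjusted over the list alone), with a median log2 fold change of 0.74 and camera's adjusted p = 3.42e-07 (adjusted p = 0.480 with an estimated correlation). The glucose transporter SLC2A3 rose by 2.22 ± 0.37 SE, the aldolase ALDOC by 2.38 ± 0.49 SE and the phosphofructokinase PFKL by 0.87 ± 0.16 SE on the log2 scale. The 1 fall, of the lactate transporter SLC16A1 (−0.46), is named after its value was seen. Relative to all libraries, the list median of the library labelled GSI 12 h and numbered 2 was 0.12, against 0.78 and 0.57 in the other 2 libraries of that group. Of the hypoxia response list, chosen after the data were seen, 25 of 29 kept genes rose and 0 fell (28 and 0 when adjusted over the list alone), with a median of 1.98 and camera's adjusted p = 8.28e-17 (adjusted p = 0.404 with an estimated correlation). Its median relative to all libraries was 0.19 in the GSI 12 h library numbered 2, against 1.64 and 1.77 in those numbered 1 and 3. The mitophagy receptors BNIP3, which rose from 420.6 ± 46.6 to 8421 ± 5287 (SD, n = 3), and BNIP3L (2.74) led the autophagy and lysosome list. Of this list 8 of 21 genes rose and 1 fell (8 and 3 over the list alone), with camera's adjusted p = 0.0283 and adjusted p = 0.469 with an estimated correlation. With the replicate block the list was not called (camera adjusted p = 0.0645). The 1 fall, SQSTM1 (−0.38), is named after its value was seen. CTSB, a lysosomal protease, rose by 0.56.

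Ribosome biogenesis genes were lower in libraries labelled GSI at 12 h in 27 of 29 cases, 28 over the list alone, with a median of −0.84 (camera adjusted p = 1.45e-19, and adjusted p = 0.469 with an estimated correlation). The leading members were RRP12 (−1.38 ± 0.16 SE), MYBBP1A (−1.07 ± 0.14 SE) and UTP20 (−1.02 ± 0.11 SE). These genes serve the processing of ribosomal RNA. Of the small nucleolar RNA host transcripts, 7 of 14 fell (7 over the list alone; median −0.33, camera adjusted p = 0.00223, and adjusted p = 0.469 with an estimated correlation), with SNHG16 at −0.78, SNHG15 at −0.70 and SNHG7 at −0.65. FOXO and quiescence genes rose in 4 of 20 cases (4 over the list alone; camera adjusted p = 0.00448, and adjusted p = 0.469 with an estimated correlation), namely the PI3K inhibitor PIK3IP1 (1.69), the cyclin CCNG2 (0.96), the antiproliferative BTG2 (0.83) and, named after its value was seen, SESN3 (0.62). Of the ATF4 stress response list, 2 of 10 rose, DDIT4 (2.31) and VLDLR (1.76), 2 over the list alone, with SESN2 at 1.61 (adjusted p = 0.0849). Camera gave the ATF4 list an adjusted p = 0.0215, and adjusted p = 0.929 with an estimated correlation. Of the NOTCH1 target genes, 7 of 16 fell and 0 rose (8 and 0 over the list alone; camera adjusted p = 0.00893, and adjusted p = 0.469 with an estimated correlation). The falls were HEY2 (−1.45), NRARP (−0.96), HES5 (−0.74), NOTCH1 itself (−0.67), MYC (−0.53), DTX1 (−0.49) and SHQ1 (−0.48). HES1 (0.15), HES4 (−0.17), HEY1 (−1.13), HEYL (0.0085), NOTCH3 (−0.14), PTCRA (−0.61), IL7R (0.081), CR2 (0.026) and IGF1R (0.013) did not pass.

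Across all genes at 12 h, limma called 4144 of 19281, 1943 higher and 2201 lower in libraries labelled GSI, and 743 and 351 of these differed at least 2-fold. Upper-quartile scaling moved the split to 1441 higher and 3704 lower. The count was 2607 with only the groups compared, 1760 without the DMSO 12 h library numbered 2, 1607 without the GSI 12 h library numbered 1 and 2343 without the GSI 12 h library numbered 3. It was 6951 with the replicate block and 5663 without the GSI 12 h library numbered 2.

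**Figure D2:**
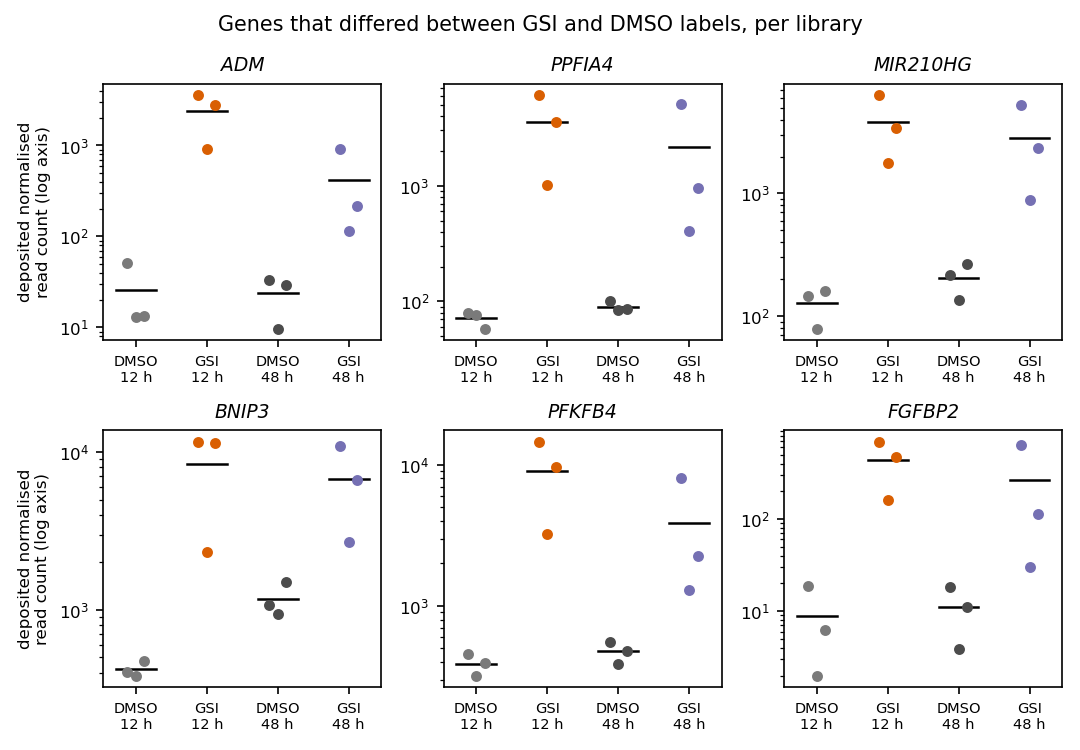
Deposited normalised read counts (log axis) of 6 genes that rose between DMSO and GSI labels at 12 h, in each of the 12 libraries, with points for libraries and black lines for group means. ADM means were 25.6 and 2426 in libraries labelled DMSO and GSI at 12 h, and 24.1 and 417 at 48 h.

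At 48 h, of the genes called with at least a 2-fold difference, 346 were higher and 207 lower in libraries labelled GSI. TBX18, a T-box transcription factor, fell from 600.0 ± 275.7 to 24.2 ± 5.84 (SD, n = 3; log2 fold change −4.50 ± 0.34 SE, adjusted p = 0.000114). GZMA, a cytotoxic granule protease, fell from 155.1 ± 68.4 to 6.39 ± 1.19 (−4.33 ± 0.38 SE). The other large falls were KCNJ2 (−3.55), the kinase PRKCE (−3.36), DMBT1 (−3.08) and ENPP1 (−2.99). PPFIA4 (3.78), ADM (3.67), FGFBP2 (3.66), MIR210HG (3.48), the circadian repressor BHLHE40 (3.09) and CIART (2.94) rose most. Of the added hypoxia list, 11 of 29 genes rose, among them AK4 (2.63) and BNIP3L (2.05), both named after their values were seen, and 17 when adjusted over the list alone. Its median was 1.40 (camera adjusted p = 3.33e-11, and adjusted p = 0.550 with an estimated correlation). Relative to all libraries, the hypoxia list median was −0.20 in the GSI 48 h library numbered 2, against 1.13 and 0.50 in those numbered 1 and 3.

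Ribosome biogenesis genes fell in 20 of 29 cases at 48 h (27 over the list alone; median −0.59, camera adjusted p = 8.58e-16, and adjusted p = 0.553 with an estimated correlation), with RRP12 at −1.06, PES1 at −0.83 and UTP20 at −0.78. Heat shock and unfolded protein response genes fell in 5 of 20 (10 over the list alone; camera adjusted p = 0.000259, and adjusted p = 0.553 with an estimated correlation), led by the chaperones HSPA8 (−1.23), HSPH1 (−0.94) and HSPE1 (−0.92), with HSPD1 (−0.71) and HSP90AB1 (−0.61) named after their values were seen. Of the mitosis list 1 of 28 fell, the cyclin CCNA2 (−0.37), 0 over the list alone, with CDK1 at −0.28 and UBE2C at −0.48 short of the threshold (median −0.24, camera adjusted p = 0.00131, and adjusted p = 0.679 with an estimated correlation). Of the DNA replication list 3 of 28 fell (6 over the list alone; camera adjusted p = 0.00160, and adjusted p = 0.679 with an estimated correlation), namely CCNE2 (−0.56), RRM2 (−0.41) and SLBP (−0.27). FOXO and quiescence genes rose in 4 of 20 (5 rose and 1 fell over the list alone; camera adjusted p = 0.00549, and adjusted p = 0.553 with an estimated correlation), among them PIK3IP1 at 2.03, BTG2 at 0.96 and, named after its value was seen, CCNG2 at 0.67. Of the glycolysis list 1 of 21 rose, PFKL (0.56), 0 over the list alone, with PFKM at 0.43 and SLC2A3 at 1.11 short of the threshold (median 0.37, camera adjusted p = 0.00636, and adjusted p = 0.679 with an estimated correlation). Relative to all libraries, the glycolysis list median was 0.34, −0.35 and −0.047 in the GSI 48 h libraries numbered 1, 2 and 3, against −0.46, −0.39 and −0.25 in the DMSO 48 h libraries, so that numbered 2 lay within the DMSO range. The interferon response list had 2 falls, USP18 (−1.03) and IFIT3 (−1.30), and 1 rise, STAT2 (0.30), among 27 (3 falls and 1 rise over the list alone; camera adjusted p = 0.0262, and adjusted p = 0.679 with an estimated correlation). Of the nuclear-encoded respiratory chain list 2 of 21 fell (2 over the list alone), CYC1 (−0.65) and NDUFS3 (−0.44), with NDUFA9 at −0.30 (adjusted p = 0.0703). Camera gave the respiratory chain list an adjusted p = 0.0156, and adjusted p = 0.685 with an estimated correlation. The small nucleolar RNA host list had falls of SNHG7 (−0.48) and SNHG15 (−0.44) among 14 (3 over the list alone), with SNHG16 at −0.48 (adjusted p = 0.0682). Camera gave the host list an adjusted p = 0.0252, and adjusted p = 0.664 with an estimated correlation.

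NOTCH1 target genes fell in 3 of 16 cases at 48 h (5 over the list alone; camera adjusted p = 0.00636, and adjusted p = 0.553 with an estimated correlation), namely NRARP (−0.83), SHQ1 (−0.55) and DTX1 (−0.49). Some fits with 1 library left out called fewer. In these, 0 target genes passed without the DMSO 48 h library numbered 1 or 2 or the GSI 48 h library numbered 1 or 3. The smallest adjusted p of a target gene in limma was then 0.0697, 0.0785, 0.0608 and 0.0846, in that order. Without the GSI 48 h library numbered 2 or the DMSO 12 h library numbered 3, 2 passed. Whether smaller groups alone cost these calls was not tested. Relative to all libraries, the list median was −0.38, −0.38 and −0.90 in the DMSO 48 h libraries numbered 1, 2 and 3, against −0.96, −0.98 and −0.78 in the GSI 48 h libraries. The list was thus not lower under the GSI label in the pair numbered 3. The values of the others, none called, were −0.33 for HES1, −0.34 for HES4, −0.28 for HES5, −1.21 for HEY1, −1.08 for HEY2, 0.089 for HEYL, −0.31 for NOTCH1, 0.43 for NOTCH3, −0.54 for PTCRA, −0.35 for MYC, −0.38 for IL7R, 0.34 for CR2 and −0.075 for IGF1R. The recombinase RAG1 (0.93) and the chromatin organiser SATB1 (1.10) rose, and CCND1, a D-type cyclin, fell by 1.96 on the log2 scale. With the replicate block the MHC class I list was called as well (camera adjusted p = 0.0252, against 0.0799 without it, and 0.519 with the block and an estimated correlation).

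In all, limma called 1866 genes at 48 h, 834 higher and 1032 lower, and 5261 with the replicate block. Upper-quartile scaling gave 741 higher and 1794 lower, and DESeq2 on recovered reads called 3242. The count was 249, 405 and 889 without the DMSO 48 h libraries numbered 1, 2 and 3, and 136, 3038 and 119 without the GSI 48 h libraries numbered 1, 2 and 3. Without both libraries numbered 2 and labelled GSI it was 4042.

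**Figure D3:**
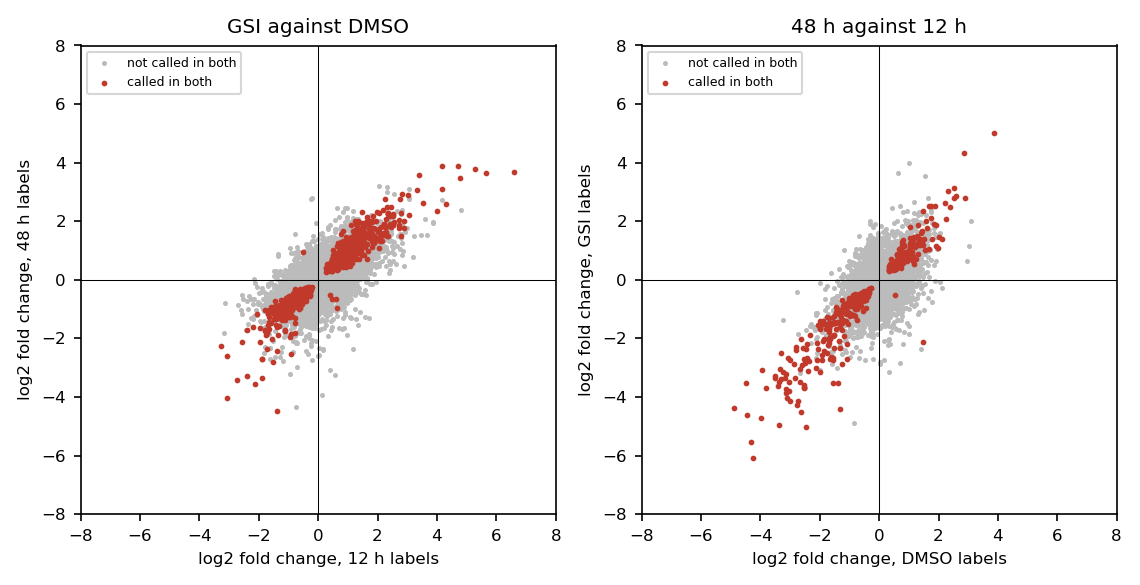
Log2 fold changes of the 19281 genes, for GSI against DMSO at 12 h (x) and 48 h (y) on the left and for 48 h against 12 h in DMSO (x) and GSI (y) on the right, with genes called in both comparisons in red. Pearson's r across genes was 0.73 on the left, where other splits of the libraries reached 0.72, and 0.59 on the right, where they reached 0.32. The other splits kept part of the label differences and are no baseline.

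Genes called in both treatment comparisons moved in the same direction with few exceptions. At both times 589 genes were higher and 723 lower in libraries labelled GSI, against 84.0 and 117.8 for independent lists, and 5 genes moved in opposite directions. Same-numbered libraries deviate together over time, so the comparisons share error. In 10 splits that moved the 12 h and 48 h libraries of a number together, at most 0 genes were called in both the same way outside the real split. Pearson's r of the fold changes across genes was 0.73, against 0.35 to 0.72 in the other splits. Spearman's rho was 0.73, against at most 0.73. The other splits mixed both labels in each part. They kept some of the label difference in the fold changes, and the rest of it widened the spread behind the calls. They are therefore no baseline for the correlations or the count. How far shared error raised these correlations was not tested. The splits are also too few for a share under 0.05. The number called in both the same way was 1312, and it was 87 without the GSI 48 h library numbered 1 and 87 without that numbered 3. It was 665 without the GSI 12 h library numbered 1, 834 without the DMSO 12 h library numbered 2, and 193, 286 and 613 without the DMSO 48 h libraries numbered 1, 2 and 3. Without the GSI 12 h or the GSI 48 h library numbered 2 it was 2140 or 2002, and without both it was 3087. It was 2294 with DESeq2 and 3883 with the replicate block.

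The number of genes called for a difference between the 48 h and 12 h treatment effects depended on the model. Limma without a replicate term called 0 of 19281 genes, with 875 at an unadjusted p under 0.05, edgeR called 0 and DESeq2 61. The count was 2 without the GSI 12 h library numbered 2, 4 without the DMSO 48 h library numbered 3 and 1 without both GSI libraries numbered 2. With a block for the replicate number within each treatment, which uses the pairing of libraries over time, 1177 genes were called, 382 with a higher and 795 with a lower effect at 48 h. Camera called 15 of the 30 lists for this contrast, none of them with an estimated correlation, where adjusted p ranged from 0.375 to 0.756. It called 8 lists without the GSI 48 h library numbered 1 and 9 without the DMSO 48 h library numbered 3.

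Between the DMSO labels, 11 of 16 NOTCH1 target genes and 18 of 29 ribosome biogenesis genes were lower in the 48 h libraries (camera adjusted p = 6.67e-23 and 2.11e-23, and 0.00618 and 0.167 with an estimated correlation). EXD3 fell from 9877 ± 2603 to 338 ± 104 (SD, n = 3; log2 fold change −4.88 ± 0.23 SE, adjusted p = 1.46e-07). The other largest falls were ALDH3B2 (−4.32), NRARP (−3.82 ± 0.19 SE), the kinase WNK2 (−3.49) and the carboxypeptidase CPA4 (−3.39). The chemokine receptor CCR2 rose from 12.6 ± 7.55 to 182.4 ± 16.1 (3.88 ± 0.33 SE), followed by SCG2 (3.10), LINC00887 (2.52) and the T-cell receptor segments TRAV8-2 (2.51) and TRAJ31 (2.26).

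Of the 16 NOTCH1 target genes, 11 fell between the DMSO labels and 0 rose (13 and 0 over the list alone; camera adjusted p = 6.67e-23, and 0.00618 with an estimated correlation). Beside NRARP these were HEY1 (−3.31), DTX1 (−2.87), HES5 (−2.34), CR2 (−1.99), HES4 (−1.87), the pre-T-cell receptor alpha chain PTCRA (−1.70), MYC (−1.14), SHQ1 (−1.11), IGF1R (−0.53) and NOTCH3, which fell from 66907 ± 12468 to 16837 ± 3358 (SD, n = 3). HES1 (−0.66), HEY2 (−1.75), HEYL (−0.18), NOTCH1 (−0.0074) and IL7R (−0.16) did not pass. Ribosome biogenesis genes fell in 18 of 29 cases (29 over the list alone; median −0.58, camera adjusted p = 2.11e-23, and 0.167 with an estimated correlation), with RRP12 at −0.93, MYBBP1A at −0.86 and WDR74 at −0.63. Cytosolic ribosomal protein genes fell in 6 of 73 (48 over the list alone; median −0.26, camera adjusted p = 2.23e-23, and 0.289 with an estimated correlation), among them RPL14 (−0.40), RPL36 (−0.37) and RPL19 (−0.34). Small nucleolar RNA hosts fell in 3 of 14 cases (8 over the list alone; camera adjusted p = 1.50e-07, and 0.101 with an estimated correlation, or 0.0452 with the replicate block), namely SNHG16 (−0.74), SNHG15 (−0.57) and SNHG7 (−0.48).

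Chemokine, cytokine and receptor genes rose in 4 of 21 cases between the DMSO labels (6 rose and 1 fell over the list alone; camera adjusted p = 0.000114, and 0.0236 with an estimated correlation), with CCR4 at 2.86, TGFBR2 at 0.75, IL6ST at 0.61 and, named after its value was seen, IL2RB at 0.40. The autophagy and lysosome list had 1 rise among 21, GABARAPL1 (0.51), 1 over the list alone, with a median of 0.20 (camera adjusted p = 0.000375, and 0.0275 with an estimated correlation). CTSD was at 0.32 and not called. FOXO and quiescence genes rose in 3 of 20 (5 over the list alone; camera adjusted p = 0.000134, and 0.114 with an estimated correlation), namely CCNG2 (1.07), BTG2 (1.03) and CCR7 (0.82). Thymocyte regulators were split, with 4 rises and 2 falls among 23 (8 and 3 over the list alone; camera adjusted p = 0.0277, and 0.114 with an estimated correlation). TOX (0.94) and GATA3 (0.77) rose, as did IKZF2 (0.53) and RUNX1 (0.56), both named after their values were seen. ID1 (−1.65), an inhibitor of E proteins, fell, as did RUNX3 (−0.81), also named afterwards.

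Camera also called the mitosis list upward between the DMSO labels (median 0.19, with CDC25C at 0.43 the 1 called gene, also over the list alone; adjusted p = 0.000155, and 0.641 with an estimated correlation). It called tRNA synthetases downward (−0.23, with VARS1 at −0.60 the 1 called gene, also over the list alone; adjusted p = 0.00116, and 0.591 with an estimated correlation). Cholesterol synthesis was called upward (0.17, 0 genes called either way; adjusted p = 0.0238, and 0.737 with an estimated correlation) and the nuclear-encoded respiratory chain downward (−0.10, 0 genes called either way; adjusted p = 0.0374, and 0.737 with an estimated correlation). The D cyclin and CDK inhibitor list (0.25; camera adjusted p = 0.0442, and 0.289 with an estimated correlation) had rises of the CDK4/6 inhibitors CDKN2D (0.68) and CDKN2C (0.47) and a fall of CCND1 (−1.32), 6 rises and 1 fall over the list alone. With the replicate block the D cyclin list was not called (camera adjusted p = 0.0642). The amino acid supply list (0.0406) and the list of replication-dependent histones (0.0497) were, both with adjusted p = 0.493 with an estimated correlation. Transcripts of these histones are poorly polyadenylated, so their values in poly-A selected libraries are uncertain. Limma called 874 genes between the DMSO labels, 391 higher and 483 lower at 48 h, 2368 with the replicate block and 5622 with a block for the replicate number within each treatment. The count was 1560 with DESeq2, 352 and 468 without the DMSO 12 h libraries numbered 2 and 3, and 499, 458 and 470 without the DMSO 48 h libraries numbered 1, 2 and 3.

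**Figure D4:**
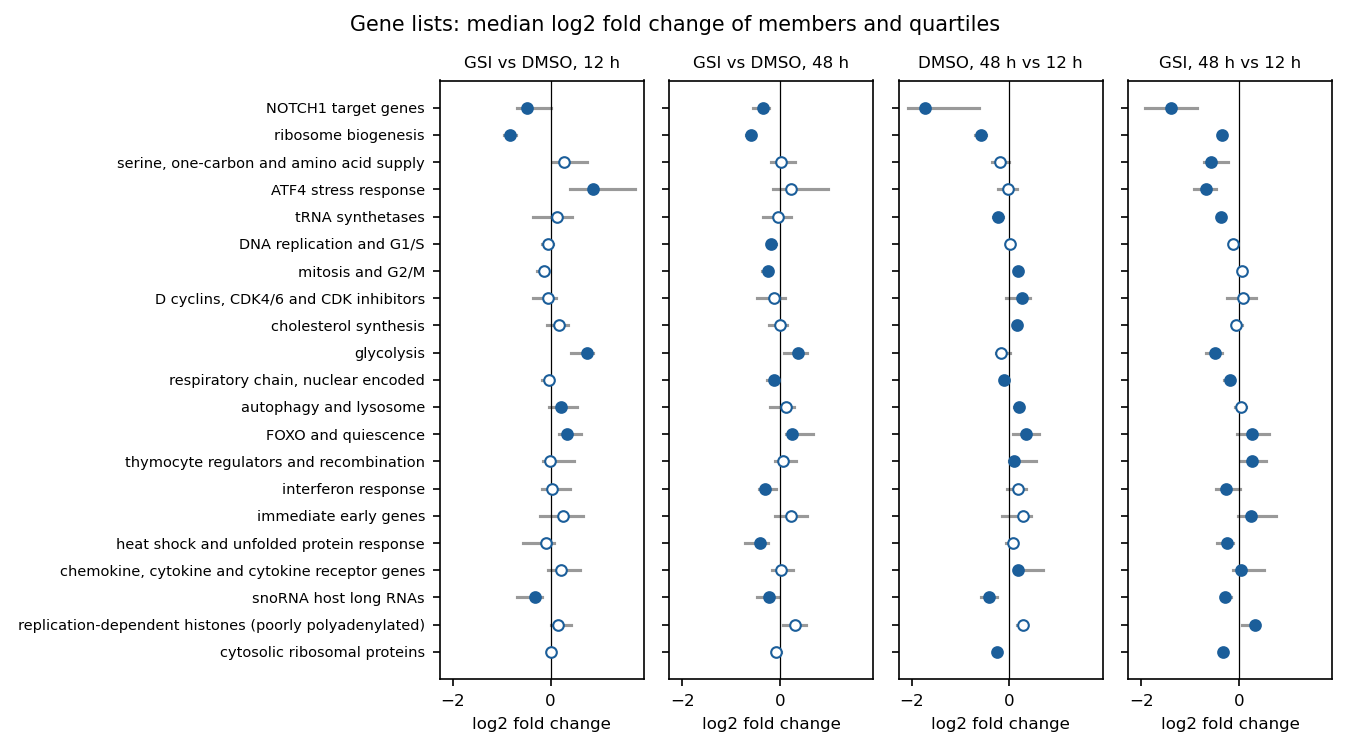
Median log2 fold change (points) and quartiles (grey lines) of the members of the gene lists called by camera in at least 1 of the 4 comparisons between groups, with filled points where camera at its preset correlation gave an adjusted p under 0.05. The NOTCH1 target genes had medians of −0.49 and −0.35 between the treatment labels and of −1.72 and −1.40 between the time labels.

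The comparison of the 48 h and 12 h libraries labelled GSI was added after the data were seen. CCR2 rose from 10.1 ± 2.30 to 358.7 ± 52.7 (SD, n = 3; log2 fold change 5.03 ± 0.33 SE, adjusted p = 1.89e-06), followed by CCR4 (4.34), the immediate early gene EGR2 (3.99), KRT1 (3.56) and TRAV8-2 (3.14). The largest falls were ALDH3B2 (−5.55), RGS6 (−5.04), TBX18 (−4.41), EXD3 (−4.37) and the immunoglobulin segment IGHV3-38 (−4.05). NOTCH1 target genes fell in 12 of 16 cases (14 fell and 1 rose over the list alone; camera adjusted p = 1.32e-21, and 0.00736 with an estimated correlation, or 0.0523 when the replicate block was added). These were NRARP (−3.69), HEY1 (−3.39), DTX1 (−2.87), HES4 (−2.04), HES5 (−1.89), CR2 (−1.69), PTCRA (−1.63), NOTCH3 (−1.42), SHQ1 (−1.18), HES1 (−1.14), MYC (−0.95) and IGF1R (−0.61). HEY2 (−1.37), HEYL (−0.10), NOTCH1 (0.35) and IL7R (−0.61) did not pass.

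Thymocyte regulators rose in 7 of 23 cases and fell in 3 between the GSI labels (12 and 3 over the list alone; camera adjusted p = 0.000108, and 0.0259 with an estimated correlation, or 0.0523 with the replicate block). RAG1 (1.43) and GATA3 (1.18) rose, and ID1 (−2.71) fell. FOXO and quiescence genes rose in 4 of 20 (4 rose and 1 fell over the list alone; camera adjusted p = 0.000699, and 0.263 with an estimated correlation), among them BTG2 (1.16), CCR7 (0.82) and CCNG2 (0.78). Of the immediate early list 3 of 19 rose and 1 fell (7 and 1 over the list alone; camera adjusted p = 0.00173, and 0.287 with an estimated correlation), with EGR3 at 2.52 and FOSL2 at −1.68 beside EGR2, and NR4A1 at 0.88 named after its value was seen. Chemokine, cytokine and receptor genes rose in 4 of 21 (5 rose and 1 fell over the list alone), with CCR9 at 1.53, TGFBR2 at 0.52 and, named afterwards, LTB at 1.12 beside CCR4. Camera gave this list an adjusted p = 0.0332, and 0.263 with an estimated correlation, or 0.0643 with the replicate block.

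Between the GSI labels, ribosome biogenesis genes fell in 3 of 29 cases at 48 h (9 over the list alone; median −0.34, camera adjusted p = 7.27e-11, and 0.412 with an estimated correlation), namely PPAN (−0.82), PES1 (−0.55) and FBL (−0.47). Cytosolic ribosomal protein genes fell in 21 of 73 (66 over the list alone; median −0.32, camera adjusted p = 1.86e-33, and 0.263 with an estimated correlation), with RPS19 at −0.53, RPS2 at −0.50 and RPL36 at −0.47. Glycolysis genes fell in 5 of 21 (12 over the list alone; median −0.49, camera adjusted p = 1.30e-09, and 0.287 with an estimated correlation), with LDHA at −0.72, ALDOA at −0.55, PGAM1 at −0.43 and, named after their values were seen, PKM at −0.55 and PFKM at −0.50. The nuclear-encoded respiratory chain had 1 fall, UQCRC1 (−0.36), among 21 (3 over the list alone; median −0.18, camera adjusted p = 1.37e-05, and 0.494 with an estimated correlation). The hypoxia list chosen after the data were seen had falls of EGLN3 (−3.52) and LDHA among 29 (5 over the list alone; median −0.61, camera adjusted p = 1.86e-07, and 0.474 with an estimated correlation).

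In all, between the GSI labels limma called 768 genes, 312 higher and 456 lower at 48 h, 1941 with the replicate block and 5544 with a block within each treatment. The count was 1261 with DESeq2, 477 with only the groups compared, 485 without the GSI 12 h library numbered 1, 446 without the GSI 48 h library numbered 3 and 427 without both GSI libraries numbered 2. Between the 2 comparisons over time, 160 genes were higher and 231 lower in both, against 6.33 and 11.4 for independent lists, with a Pearson's r of 0.59 and a Spearman's rho of 0.44 across genes. In 10 splits that moved the DMSO and GSI libraries of a number together, the highest other values were 0 genes, an r of 0.32 and a rho of 0.34. These splits, also too few for a share under 0.05, mixed both time labels in each part and are no baseline. The 391 genes called in the same direction in both comparisons over time became 249 without the DMSO 12 h library numbered 2 and 668 with DESeq2. They became 1057 with the replicate block and 2972 with a block within each treatment.

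Long non-coding RNAs were called less often than protein-coding genes in both treatment comparisons, and those called were more often higher in libraries labelled GSI, which was not so between the time labels. At 12 h, 527 of 2987 (17.6%) long non-coding genes were called against 3257 of 13445 (24.2%) protein-coding genes (odds ratio 0.67, Fisher's exact test adjusted p = 5.84e-15, described across genes). At 48 h the shares were 6.26% and 11.4% (odds ratio 0.52, adjusted p = 1.24e-17). Between the DMSO labels they were 2.54% and 5.32% (odds ratio 0.46, Fisher's exact test adjusted p = 1.00e-11). Between the GSI labels they were 2.61% and 4.46% (odds ratio 0.58, Fisher's exact test adjusted p = 1.60e-06). Of the called long non-coding genes 371 were higher and 156 lower at 12 h, against 1359 higher and 1898 lower protein-coding genes (odds ratio 3.32), and at 48 h 139 were higher and 48 lower, against 592 and 937 (odds ratio 4.58). Within strata of the mean value the odds ratio at 12 h was 1.56. Upper-quartile scaling moved the shares higher from 70.4% and 41.7% to 55.9% and 23.1%. Between the DMSO labels 27 called long non-coding genes were higher and 49 lower at 48 h (odds ratio 0.61, Fisher's exact test adjusted p = 0.0713). Between the GSI labels 26 were higher and 52 lower (odds ratio 0.69, adjusted p = 0.178). The treatment direction therefore holds for the labels as given, which an exchange would turn into a direction over time. The median value was 46.2 for long non-coding and 2535 for protein-coding genes, so fewer reads stood behind the former. At 12 h LINC02649 (3.06 ± 0.83 SE) and MRPL23-AS1 (3.01 ± 0.71 SE) rose most after MIR210HG. LINC01483 (−2.41 ± 0.60 SE), LINC01963 (−1.58 ± 0.21 SE) and LINC01341 (−1.43 ± 0.22 SE) fell most. At 48 h the largest rises after MIR210HG were MRPL23-AS1 (2.89) and KDM7A-DT (2.26), and the largest falls LINC01483 (−3.28), LINC00689 (−1.29) and LINC01341 (−1.04). Of long non-coding RNAs named in leukaemia or T cells, a list not called by camera in either comparison, HOTAIRM1 rose at both times (0.95 and 0.77), NEAT1 at 12 h (1.26) and MIAT at 48 h (0.72), and NALT1, named after its value was seen, at 12 h (0.82). Between the DMSO labels LINC01120 fell from 524.1 ± 220.8 to 49.1 ± 15.5 (SD, n = 3; log2 fold change −3.32 ± 0.36 SE), with further falls of LINC02762 (−2.64) and LINC01694 (−2.44), while LINC00892 (1.53) and PROX1-AS1 (1.37) rose. Between the GSI labels LINC00887 (2.80), LINC00892 (1.39) and LINC01801 (1.25) rose most. LINC01120 (−3.06), LINC02763 (−2.49) and CHRM3-AS2 (−2.45) fell most.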

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

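All tests on the NOTCH1 target and glycolysis patterns in this part were chosen after the results were seen. The other splits of the libraries were set before the results of those splits were seen. The comparison between the GSI labels, which they include, was itself added after the data were seen.

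Camera's test of the difference between the 48 h and 12 h treatment effects passed for 15 lists fixed beforehand, and 1 added list did as well. The median difference in log2 fold change was −0.75 for the ATF4 stress response, −0.47 for NK and innate lymphoid markers, −0.34 for glycolysis, −0.29 for the interferon response, −0.24 for heat shock, −0.19 for mitochondrially encoded genes and −0.17 for cholesterol synthesis. It was −0.15 for autophagy and lysosome, −0.12 for DNA replication, −0.083 for mitosis, −0.078 for the respiratory chain, −0.076 for D cyclins and CDK inhibitors, and −0.060 for cytosolic ribosomal proteins. It was 0.24 for ribosome biogenesis and 0.15 for small nucleolar RNA hosts, and −0.65 for the hypoxia list chosen after the data were seen. None of these passed with an estimated correlation, where adjusted p ran from 0.375 to 0.756. With the replicate block the D cyclin list did not pass at the preset correlation (adjusted p = 0.0618), and the amino acid supply list did (0.0119, against 0.0600 without the block), though not with an estimated correlation (0.453).

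Splits of 6 libraries into 3 and 3 number only 10, too few for a share under 0.05. The real split called 4144 genes at 12 h, 1866 at 48 h, 874 between the DMSO labels and 768 between the GSI labels, in each case 1 of 10 splits with as many. The highest other split called 0, 0, 0 and 32 genes. At 48 h and in both comparisons over time, where the numbers pair the libraries, the other splits that part every same-numbered pair called at most 0. Every other split of 6 libraries mixed both groups in each part, so that a true difference widens the spread and lowers the count. Their counts are therefore no baseline. For the difference between treatment effects the real count was 0, which all 100 drawn splits reach by definition, so the splits say nothing there. The highest other drawn split called 2131 genes and points to a structure of the samples. It exchanged the time labels of all 6 libraries labelled GSI, and so added the changes over time instead of subtracting them.

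NOTCH1 target genes differed more between the time labels than between the treatment labels. Under the other scalings the list median between the DMSO labels was −1.71 at the nearest to 0, so those tried left the fall in place. A factor per library shifts all genes nearly alike, which fixed the distance of the list from all genes beforehand. That distance is therefore no test of the scaling. Open are an exchange of the labels GSI 12 h and DMSO 48 h in all 3 replicates, and labels as given with NOTCH1 targets falling over time in both treatments. The list median of −1.40 between the GSI labels is part of the pattern itself, so it is no test of the latter. The 2 explanations cannot be told apart. Same-numbered libraries deviated together most within a treatment label (lowest correlation 0.400, against at most 0.272 within a time label). An exchange may produce this through shared harvests, but repeated sampling of 1 culture could as well.

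Glycolysis genes were higher in libraries labelled GSI at 12 h. Lower depth of those libraries is argued against, since on reads thinned to the shallowest library the list median was 0.75 (lower quartile 0.43). Under the other scalings the lowest median was 0.64 (lower quartile 0.32), so those tried left the rise in place. As above, the distance of the list from all genes is no test of the scaling. An effect of the inhibitor, with a list median of 0.37 at 48 h, where 1 GSI library lay within the DMSO range, stays open. So does an exchange of labels, under which the 12 h comparison could hold time in culture instead. The list median of −0.17 between the DMSO labels would then hold the inhibitor's change, so it is no test of an exchange. The design confounds an inhibitor effect and an exchange of labels, and they cannot be told apart.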

How the results depend on the processing

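The count of genes called moved with the model and with single libraries. At 12 h the 4144 calls became 6951 with a replicate block, 2607 with only the groups compared, 1259 at an adjusted p under 0.01 and 1094 at 2-fold or more, and 1607 to 5663 with a library left out. At 48 h the 1866 became 5261 with the block, 3242 with DESeq2, 4042 without both GSI libraries numbered 2, 138 at an adjusted p under 0.01, 553 at 2-fold or more, and 119 to 3038 with a library left out. The count of 0 for the difference became 40 with the block, 1177 with a block within treatment, 61 with DESeq2, 1 without both GSI libraries numbered 2 and 0 to 4 with a library left out, and this difference could not be fitted with only the groups compared.

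Between the DMSO labels the 874 became 2368 with the block, 5622 with a block within treatment, 1560 with DESeq2, 311 at an adjusted p under 0.01, 300 at 2-fold or more, and 352 to 1068 with a library left out. Between the GSI labels the 768 became 1941 and 5544 with these blocks, 1261 with DESeq2, 477 with only the groups compared, 427 without both GSI libraries numbered 2, 347 at an adjusted p under 0.01, 370 at 2-fold or more, and 446 to 734 with a library left out. Genes shared by the treatment comparisons numbered 3883 with the block, 2294 with DESeq2, 3087 without both GSI libraries numbered 2 and 87 to 2140 with a library left out. Those shared by the comparisons over time numbered 1057 and 2972 with the blocks, 668 with DESeq2 and 249 to 414 with a library left out.

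With an estimated correlation camera called 0 lists at 12 h, 0 at 48 h, 0 for the difference, 3 between the DMSO labels and 2 between the GSI labels, and fry called 7, 5, 0, 8 and 5. With a library left out the preset camera called 6 to 9, 7 to 13, 8 to 15, 11 to 18 and 13 to 18 lists in the same order. The autophagy list at 12 h was lost with the block (adjusted p = 0.0645). The odds ratio of long non-coding against protein-coding calls was 0.855 and 0.653 at a filter of 50. No named gene reversed its direction while called. Of 405 results for named genes, 67 not called in the main fit were called with the replicate block. With the block within treatment, 79 of 207 results over time were called that the main fit did not call. Why a left-out library moved a count was not tested.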

Other observations

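The tests of level and scaling in this part were set before their results were seen; the pattern they address was noticed in the data.

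Immediate early genes, a list not called by camera in either treatment comparison, held single large changes. At 48 h NR4A1, an orphan nuclear receptor, rose from 97.5 ± 18.9 to 390.6 ± 51.9 (SD, n = 3) and EGR3 by 2.46 ± 0.33 SE (log2) in libraries labelled GSI, with EGR1 (1.97) and EGR2 (2.80) also called and DUSP5 (−0.66) lower, the last 3 named after their values were seen. At 12 h NR4A1 rose by 1.24 and DUSP2 fell by 0.69. Of 25 T-cell receptor and surface marker genes, 3 rose and 1 fell at 48 h (3 and 1 over the list alone; camera adjusted p = 0.644). At 12 h 1 rose and 2 fell (1 and 1 over the list alone; camera adjusted p = 0.718). At 48 h CD1E (0.56), the T-cell receptor zeta chain CD247 (0.51) and CD8B (0.70) rose and CD1A (−0.39) fell. At 12 h CD8B (0.68) rose and CD3G (−0.43) and CD1A (−0.36) fell. CD1A, and CD8B at 48 h, were named after their values were seen. The coactivator MAML2 rose by 2.67 at 12 h and the Notch ligand JAG1 fell by 1.39 at 48 h, both from the Notch pathway machinery list, which camera did not call. The anti-apoptotic BCL2 fell by 0.56 and PMAIP1, a pro-apoptotic relative, by 0.65 at 48 h. Of the p53 target list, not called, CDKN1A fell by 1.00 and TNFRSF10B rose by 0.37 at 48 h, and AEN fell by 1.02 and RRM2B rose by 0.43 at 12 h.

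Markers of other cell types were scarce in these libraries: 4 of 12 B-cell, 3 of 15 myeloid, 2 of 12 erythroid and megakaryocyte, and 3 of 14 stromal and epithelial markers were kept, too few to test. Of 8 kept NK and innate lymphoid markers, EOMES fell at 12 h (−0.76) and 48 h (−1.32), NKG7 fell at 48 h (−0.87) and PRF1 rose at 12 h (0.97), with camera's adjusted p at 0.573 and 0.285.

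Between the GSI labels over time, the added comparison, camera also called lists in which at most 1 gene passed. Serine, one-carbon and amino acid supply had a median of −0.56 (camera adjusted p = 0.000562, and 0.539 with an estimated correlation) and the ATF4 stress response one of −0.67 (camera adjusted p = 0.00670, and 0.546 with an estimated correlation). The tRNA synthetases had −0.37 (camera adjusted p = 1.37e-05, and 0.379 with an estimated correlation) and small nucleolar RNA hosts −0.28 (camera adjusted p = 0.000550, and 0.287 with an estimated correlation). Heat shock genes had −0.25 (camera adjusted p = 0.0120, and 0.539 with an estimated correlation), with 1 fall over the list alone. Replication-dependent histone genes had 0.32 (camera adjusted p = 0.0238, and 0.412 with an estimated correlation). Their transcripts are poorly polyadenylated, so their values in poly-A selected libraries are uncertain. The interferon response had −0.26 (camera adjusted p = 0.0450, and 0.578 with an estimated correlation), although its 1 called gene, STAT2 (0.32), rose. With the replicate block the DNA replication and mitochondrially encoded lists were called too (camera adjusted p = 0.0131 for both, against 0.0628 and 0.0502 without it, and 0.521 and 0.517 with the block and an estimated correlation).

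The 2 libraries numbered 2 and labelled GSI stood nearer the DMSO libraries in the added hypoxia list. Their list medians relative to all libraries were 0.19 at 12 h and −0.20 at 48 h, against 1.64 and 1.77 at 12 h and 1.13 and 0.50 at 48 h in the others. The 6 libraries labelled DMSO lay between −0.92 and −0.61. Without these 2 libraries, a choice made after their values were seen, the list did not pass with an estimated correlation either (adjusted p = 0.0811 at 12 h and 0.125 at 48 h).

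Called long non-coding RNA genes were more often higher than called protein-coding genes at 12 h, with an odds ratio of 3.32. Their lower expression level may account for part of this, since within strata of the mean value the odds ratio was 1.56 (95% interval 1.24 to 1.97). The interval lay above 1, but it counts called genes as independent, and level may still differ within strata. It therefore cannot decide whether level is the whole cause. The deposited scaling is argued against, with an odds ratio of at least 3.38 under the other scalings. Whether any remainder reflects the inhibitor or the label question above was not tested.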
